A study of Mus musculus with 12 samples.

How the data were processed

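RNA sequencing libraries were made from T cells that had been surface-stained and sorted by flow cytometry from the kidney and the spleen of MRL/lpr mice aged 23 weeks, per the labels' protocols. MRL/lpr mice carry the lpr mutation of Fas, the death receptor of lymphocytes, and develop a lupus-like disease with nephritis. RNA was isolated with a micro-scale column kit and amplified from low input with SMART-Seq v4 chemistry, per the labels' protocols. The labels gave 4 groups of 3 libraries each, CD4 kidney, CD4 spleen, CD8 kidney and CD8 spleen, and every group used the replicate numbers 1, 2 and 3.

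The submitters' processing notes name FastQC 0.11.5, cutadapt 1.8.3, STAR 2.6.0c, featureCounts, Subread 1.6.2, limma and the genome build mm10. The authors deposited 1 table of log2 values per library, with 15814 genes and 3 decimals. No header states the scale. The antilogs (2 to the value) summed to between 952833 and 1041020 per library, close to log2 CPM. Sequencing depth per library is unknown, so no counting interval is given. A count test had been planned as the first choice, with limma on the log2 scale as the fallback for normalized values, and the fallback was used.

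The deposited values held a centring that no label or header mentions. Every gene had the same mean, to within 0.00075, in each of 3 sets of 4 libraries, and the gene-centred values had rank 9 where 12 separate libraries give 11. The first set held the libraries labelled CD4 kidney 1 and 2 and CD4 spleen 1 and 2. The second held CD4 kidney 3, CD8 kidney 1, CD4 spleen 3 and CD8 spleen 1, and the third CD8 kidney 2 and 3 and CD8 spleen 2 and 3. Each set had as many kidney as spleen libraries, so the centring left the averaged kidney-spleen differences in place. If cell types are as labelled, it shrank CD8-CD4 differences within a tissue. If they follow Cd4 and Cd8a, each set held 1 library of each type per tissue, and such differences were left in place. The centring also took 2 degrees of freedom that a fit by group still counts, 8 residual degrees against 6 with a term for the set. For this reason a fit with the set as a block was added after the data were seen. Its counts stand beside those of the comparisons and of some lists whose counts it changed.

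Genes were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 libraries, no replicate block, moderated variances with a trend on the mean and Benjamini-Hochberg adjustment at 0.05. No filter was applied. The contrasts were kidney minus spleen for each cell type label, their average, their difference (the interaction), and CD8 minus CD4 in each tissue. Gene lists were tested with camera at a preset correlation of 0.01 among genes, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera asks whether a list moved relative to the other genes. Of 45 lists 44 could be tested, since 0 mitochondrially encoded genes were in the tables. Of 801 list entries written 710 matched a gene, 10 of them through synonyms. Gene spans are from the RefSeq annotation of GRCm38.p6, the assembly behind mm10.

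The groups, contrasts, thresholds, gene lists, rule for named genes and first list of alternatives were fixed before the data were examined. The rule named 11 genes whatever their result, namely Cd4, Cd8a, Cd8b1, Pdcd1, Ctla4, Lag3, Havcr2, Tigit, Tox, Fas and Cd69. It further named the 5 highest and the 5 lowest called genes per comparison, without overlap between the libraries compared. These had a mean in the higher group above the median level over genes, an established symbol and no place in the lists of other cells. For each list it took up to 2 called members in the majority direction and 1 in the other direction, with the smallest adjusted p. A gene that the rule named is not reported here. Values are means ± SD over libraries and differences carry the standard error (SE) of the fit.

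The analysis was tested on simulated data with the same sets, cell types as labelled and 15814 genes. In each comparison 67, 67 and 66 genes were changed by a log2 difference of 0.5, 1 and 2. These are far fewer than were called in the data, so the shares below need not carry over to it. After centring by set, the fit by group gave false calls among 10.1% of its calls for the average, 9.68% for CD4 and 15.3% for CD8, against 3.61%, 3.77% and 7.27% with the set block. Without centring the fit by group gave 3.19%, 4.48% and 8.47%. The shares rest on few calls, after centring 11 of 109, 6 of 62 and 9 of 59. A simulated log2 difference of 1 was recovered for 58.2% of changed genes in the average, 28.4% in CD4, 22.4% in CD8 and 2.99% in the interaction. For CD8 against CD4 within a tissue a simulated log2 difference of 2 was estimated at a median of 1.35 in the kidney and 1.38 in the spleen and 0 genes were recovered. With the set block the estimates were 1.99 and 2.11, and 34.8% and 27.3% of those genes were recovered.

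Alternatives included the replicate number as a block, limma without the trend, quantile and median scaling, a filter at the median level, a fold threshold, a stricter adjusted p, removal of genes of other cells and leaving out each library in turn. Added after seeing the data were the set block, fits without the 4 libraries numbered 2, both together, a covariate for Cd8a minus Cd4, a fit of 1 paired difference per set, and a block for the 6 kidney-spleen pairs of 1 label and number. Alternatives that need counts were not run.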

Results

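The data were transcriptomes of sorted CD4 and CD8 T cells from the kidney and the spleen of lupus-prone MRL/lpr mice, 12 libraries in 4 groups of 3. The series title describes kidney-infiltrating and splenic T cells as paired, and the comparison of the 2 tissues is its main question. Values are log2 on a scale close to CPM (library-size-scaled read counts), over 15814 genes, and the depth of each library is unknown. Nothing in the labels ties a library to 1 animal, so p-values measure the spread between these samples, which may be technical.

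The lineage genes split the libraries along lines other than their labels. Cd4, the coreceptor of helper T cells (chromosome 6, 124864693 to 124888247, mm10), was at 10.58 and 10.16 in the libraries labelled CD4 kidney 1 and 3 and at 10.30 and 10.12 in CD4 spleen 1 and 3. In CD4 kidney 2 and CD4 spleen 2 it was at 2.55 and -2.38, while Cd8a, the coreceptor chain of cytotoxic T cells (chromosome 6, 71373427 to 71379171), was at 10.44 and 9.99. The libraries labelled CD8 kidney 2 and CD8 spleen 2 held the opposite, with Cd4 at 11.41 and 11.28 and Cd8a at 1.01 and 0.41. CD8 kidney 1 and 3 and CD8 spleen 1 and 3 had Cd8a between 9.61 and 10.16 and Cd4 between -1.78 and 0.71. Groups were kept as labelled, so "labelled CD4" and "labelled CD8" below mean 2 libraries with the labelled marker and 1 with the other marker in each tissue. The estimate of the average over both labels does not depend on the cell type labels. Its SE and its calls do, since the spread is taken within the labelled groups.

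**Figure D1:**
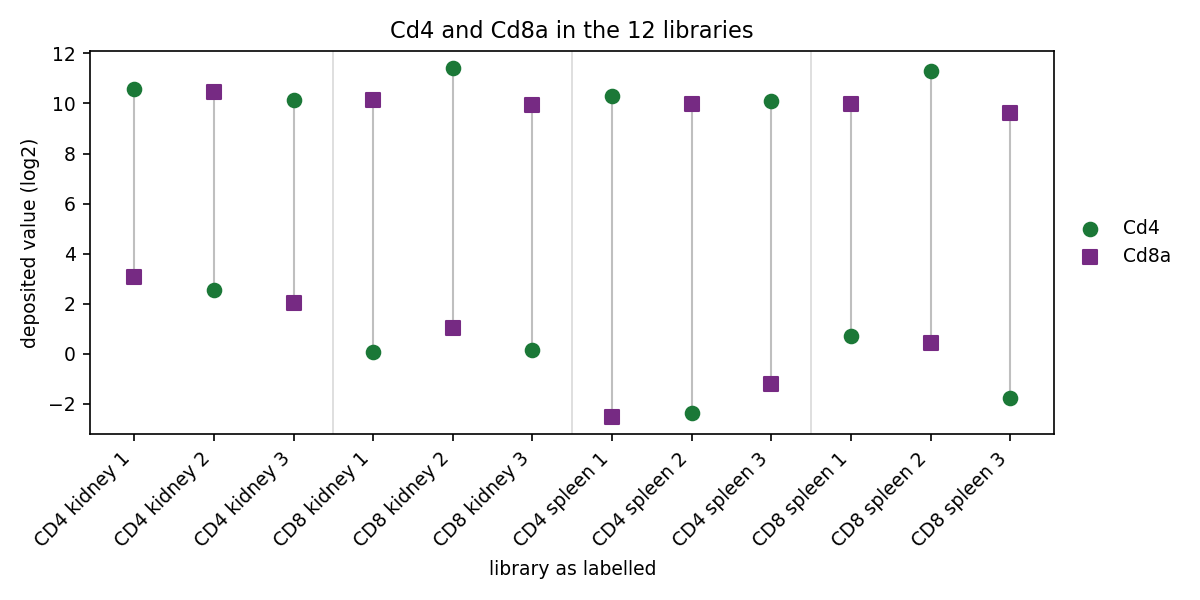
Cd4 and Cd8a (log2 value) in each of the 12 libraries, by labelled group and number. In the 4 libraries numbered 2 the marker of the other cell type is the higher one, by 7.89 to 12.37 log2 units.

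Averaged over both labels (6 kidney against 6 spleen libraries), 14 of 18 naive and central memory genes were lower and 5 of 15 tissue residence genes higher in kidney T cells than in splenic T cells. Neither list passed with an estimated correlation (adjusted p = 0.47 and 0.445). In that test 0 lists passed in this comparison. Even the kidney tubule markers, every one of them called higher, did not pass it (adjusted p = 0.144). Failing it therefore cannot show that a list did not move, here or in the kidney-spleen comparisons below. Bach2, a repressor of effector differentiation (chromosome 4, 32238413 to 32586109), was at 3.50 ± 0.45 in kidney and 5.96 ± 0.33 in spleen (SD, n = 6 each), a log2 difference of -2.46 (SE 0.22, limma adjusted p = 7.45e-06). Foxp1, a transcription factor of T cell quiescence (chromosome 6, 98925342 to 99522746), fell from 8.02 ± 0.15 to 6.72 ± 0.13 (SD, n = 6 each; limma adjusted p = 1.13e-06). Of 18 naive and central memory genes 14 fell and 1, Igfbp4, rose by 2.41 (SE 0.42), with 15 lower and 1 higher adjusted over the list alone and 13 and 1 with the set block. Igfbp4 was highest in CD4 kidney 3 and CD8 kidney 1 (8.06 and 7.55), the libraries with the highest tubule marker means, so its rise cannot be assigned to T cells. The list passed camera (median -1.80, adjusted p = 3.43e-04). Of 8 tissue egress genes 6 fell and 0 rose, with the same counts adjusted over the list alone. They included S1pr1, the sphingosine phosphate receptor that leads lymphocytes out of tissue, at -1.78 (SE 0.29), and the transcription factor Klf3 at -1.69 (SE 0.15). The egress list had a median of -1.74 (camera adjusted p = 0.0101; adjusted p = 0.516 with an estimated correlation) and was not called without the members it shares with other lists (camera adjusted p = 0.0865; range over its alternatives 2.09e-04 to 0.516).

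Among 15 tissue residence genes 5 rose, 0 fell and 10 did not pass, and the count was the same adjusted over the list alone. Cxcr6, a chemokine receptor of tissue-resident T cells (chromosome 9, 123806477 to 123811754), was at 10.05 ± 0.58 in kidney and 7.10 ± 0.49 in spleen (SD, n = 6 each), a log2 difference of 2.95 (SE 0.30, limma adjusted p = 1.96e-05). Itga1, the integrin chain that binds collagen (chromosome 13, 114958079 to 115101964), rose by 4.51 (SE 0.42), from 1.10 ± 0.43 to 5.60 ± 0.99. Cdh1, encoding E-cadherin (chromosome 8, 106603350 to 106670247), rose by 4.64 (SE 0.33) and is also a gene of tubule epithelium. The residence list had a median of 1.12 (camera adjusted p = 8.8e-04; adjusted p = 0.445 with an estimated correlation). Cd69, an early activation and retention marker, did not pass in the average (log2 difference -0.54, SE 0.28, limma adjusted p = 0.136).

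Pdcd1, encoding the inhibitory receptor PD-1 (chromosome 1, 94038305 to 94052553), rose in kidney, from 7.96 ± 1.14 to 9.58 ± 0.48 (SD, n = 6 each), a log2 difference of 1.61 (SE 0.47, limma adjusted p = 0.0182; 0.0347 with the set block). Entpd1, the ectoenzyme CD39, rose by 1.46 (SE 0.52, limma adjusted p = 0.0398; 0.068 with the set block), and Btla, another inhibitory receptor, fell by 1.22 (SE 0.29, limma adjusted p = 0.00682). The other inhibitory receptors fixed by name did not pass, with Ctla4 at 1.12 (SE 0.84), Tigit at 1.05 (SE 0.57), Havcr2 at 0.96 (SE 0.65) and Lag3 at 0.08 (SE 0.56). With the set block and a covariate for Cd8a minus Cd4 their SE were 0.48, 0.46, 0.59 and 0.54. They did not pass there either (limma adjusted p = 0.0654, 0.0793, 0.186 and 0.873). Over the 14 inhibitory receptors 2 rose and 1 fell, 1 and 1 adjusted over the list alone, and the list did not pass (median 0.90, camera adjusted p = 0.0783). Tox, a transcription factor of exhausted T cells, was at 0.89 (SE 0.42, limma adjusted p = 0.106). Fas, which carries the lpr mutation in this strain, was at -0.69 (SE 0.35, limma adjusted p = 0.133). The exhaustion-linked transcription factors gave 1 gene higher, Id2 (1.47, SE 0.54), and 1 lower, Eomes (-0.83, SE 0.27), of 15, with 0 and 0 adjusted over the list alone and 0 and 1 with the set block (median 0.56, camera adjusted p = 0.0906).

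Pdcd1 and Btla were called in all 12 fits that leave out 1 library. Entpd1 was not called in 8 of those fits, all but those without CD4 kidney 3, CD4 spleen 1, CD4 spleen 3 or CD8 spleen 2 (highest limma adjusted p = 0.0866), and Id2 was not called in 9, all but those without CD4 spleen 1, CD4 spleen 3 or CD8 spleen 2 (highest 0.0913). With the set block and a covariate for Cd8a minus Cd4 both were called (limma adjusted p = 0.0236 for Entpd1 and 0.00912 for Id2). They were also called with 1 paired difference per set (0.0106 and 0.00166). With kidney-spleen pairs by label and number Id2 was called (0.0307) and Entpd1 was not (0.0518; ranges over their alternatives 0.00166 to 0.26 and 0.0106 to 0.245). Eomes was not called without CD4 kidney 1, CD4 kidney 3, CD8 kidney 2, CD8 kidney 3, CD4 spleen 1 or CD8 spleen 1 (highest 0.068). Tox was called without CD8 spleen 2 (limma adjusted p = 0.0348; range over its alternatives 0.0303 to 0.683). The inhibitory receptor list passed without CD4 kidney 3, CD4 spleen 3 or CD8 spleen 2 (camera adjusted p = 0.0297, 0.0213 and 0.0282), and the exhaustion-linked list without the same libraries (0.0425, 0.0204 and 0.0151). Both also passed with kidney-spleen pairs by label and number (0.0292 and 0.0402) and over genes above the median level (0.0333 and 0.037). The inhibitory list further passed without the libraries numbered 2 once the set block was added (0.0479). Over all their alternatives these lists had an adjusted p of 0.0213 to 0.814 and 0.0151 to 0.925.

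**Figure D2:**
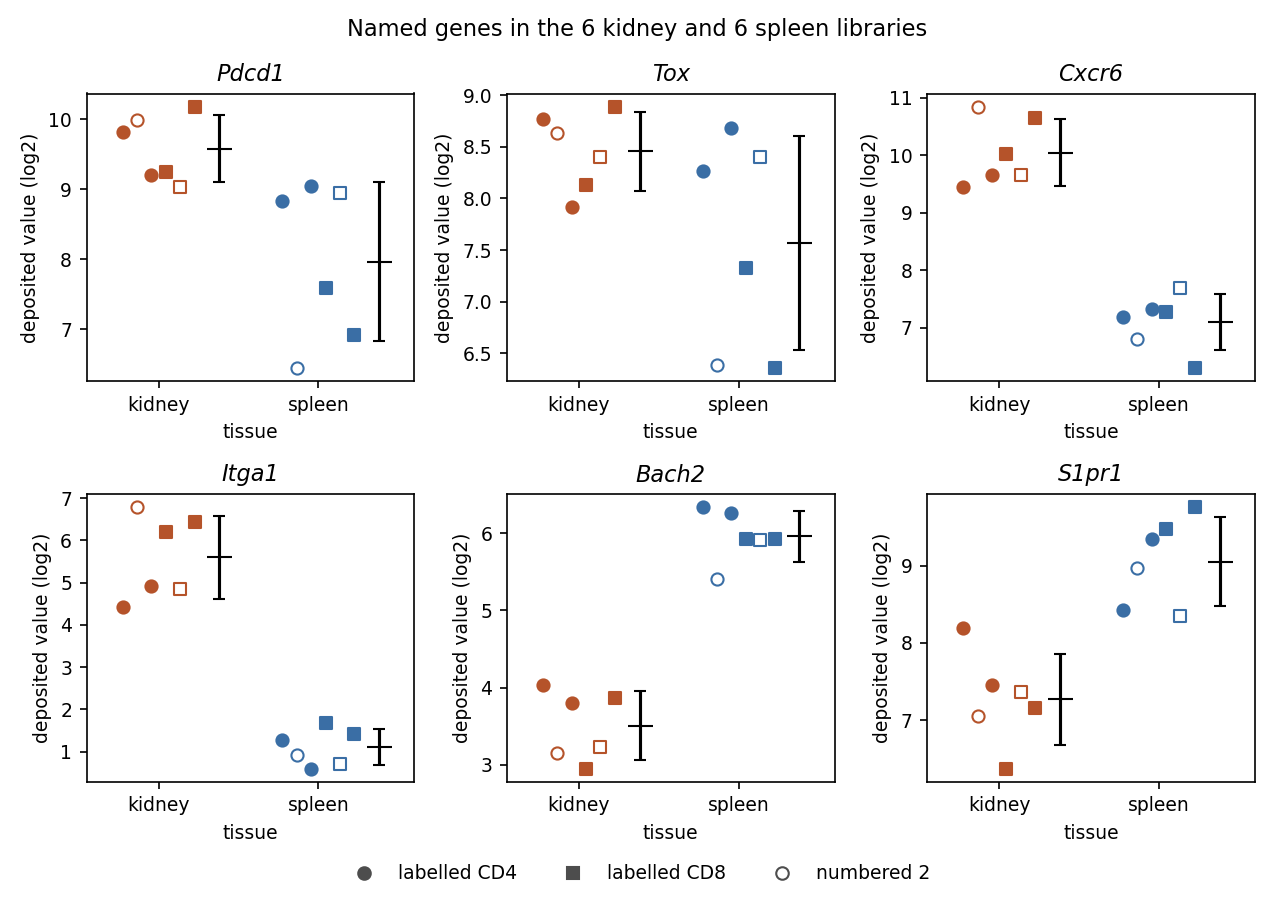
Values (log2) of Pdcd1, Tox, Cxcr6, Itga1, Bach2 and S1pr1 in each library by tissue, with the mean and SD over the libraries of each tissue (n = 6). Marker shape gives the cell type label. Cxcr6 averages 10.05 over the 6 kidney and 7.10 over the 6 spleen libraries, and Bach2 averages 3.50 and 5.96.

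Genes of mitochondrial metabolism were higher in kidney T cell libraries. Of 57 nuclear oxidative phosphorylation genes 34 rose and 0 fell (38 and 1 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 3.49e-11; adjusted p = 0.478 with an estimated correlation). Ndufb8, a subunit of complex I, rose by 0.54 (SE 0.09) and Sdhd, of complex II, by 0.72 (SE 0.12). Of 22 tricarboxylic acid cycle genes 19 rose and 0 fell, the same adjusted over the list alone (median 0.42, camera adjusted p = 1.49e-08; adjusted p = 0.431 with an estimated correlation), led by Idh1 at 3.87 (SE 0.28). Of 22 fatty acid oxidation genes 13 rose and 0 fell (14 and 1 adjusted over the list alone; median 0.63, camera adjusted p = 4.29e-06; adjusted p = 0.431 with an estimated correlation), among them Ppargc1a, a regulator of mitochondrial biogenesis, at 4.88. Of 18 redox and metal response genes 14 rose and 0 fell (17 and 0 adjusted over the list alone; median 0.60, camera adjusted p = 1.47e-07; adjusted p = 0.144 with an estimated correlation), with the metallothionein gene Mt1 at 4.32 and the ferritin gene Fth1 at 0.74. Of 25 dissociation and heat shock genes 9 rose and 0 fell, the same adjusted over the list alone (median 0.31, camera adjusted p = 8.8e-04; adjusted p = 0.393 with an estimated correlation), with the chaperone genes Hspa1a at 4.56 and Hspa1b at 4.20. All 22 kidney tubule markers also rose in the kidney libraries (median 9.63). Whether the redox and heat shock genes follow the tubule markers from library to library was not tested.

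Transcripts of other cells were among the greatest differences. Slc27a2, a fatty acid transport protein of liver and proximal tubule (chromosome 2, 126553024 to 126588243), was at 8.74 ± 0.59 in kidney and -2.51 ± 0.60 in spleen (SD, n = 6 each), a log2 difference of 11.25 (SE 0.35, limma adjusted p = 4.56e-09). The spleen value is close to the floor of the tables, so this fold depends on the offset used for log values. Fbp1 (10.57), Keg1 (10.57) and Tmem27 (10.53) were also among the highest. The tubule markers took 0.696% to 1.89% of the summed antilogs in the kidney libraries and 0.00303% to 0.0104% in the spleen libraries, and all 22 also rose adjusted over the list alone (camera adjusted p = 2.35e-31; adjusted p = 0.144 with an estimated correlation). Of 17 macrophage and monocyte markers 13 rose and 0 fell (14 and 0 adjusted over the list alone; median 2.00, camera adjusted p = 5.78e-08; adjusted p = 0.144 with an estimated correlation), with Apoe at 4.002 and Lyz2 at 2.76. Of 12 endothelial markers 8 rose and 1 fell (median 3.14, camera adjusted p = 2.13e-05; adjusted p = 0.144 with an estimated correlation), and of 11 fibroblast and mural markers 7 rose and 0 fell (median 2.19, camera adjusted p = 8.83e-05; adjusted p = 0.312 with an estimated correlation), both with the same counts adjusted over the list alone. The endothelial markers took 0.029% to 0.0527% of the summed antilogs in kidney and 0.0421% to 0.0589% in spleen. Ehd3, the called member that fell (-0.59), made up 74.5% to 87.8% of that sum in kidney and 96.3% to 99.3% in spleen. Without Ehd3 the share was 0.00431% to 0.00868% in kidney and 4.35e-04% to 0.0016% in spleen.

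Markers of B cells, neutrophils and erythroid cells were lower in kidney. Of 12 B cell markers 11 fell (12 adjusted over the list alone; median -2.82, camera adjusted p = 1.2e-04; adjusted p = 0.431 with an estimated correlation), with the B cell kinase gene Blk at -3.18 and the adaptor gene Bank1 at -3.90. Of 12 neutrophil markers 10 fell (10 adjusted over the list alone; median -3.29, camera adjusted p = 0.00263; adjusted p = 0.445 with an estimated correlation), and of 7 erythroid markers 6 fell (6 lower and 1 higher adjusted over the list alone; median -4.22, camera adjusted p = 0.00191; adjusted p = 0.431 with an estimated correlation). Some called genes lay outside the lists of other cells, did not overlap between the tissues and had a mean in the higher tissue above the median level (3.76). The lowest of these were Treml2 (-3.97, SE 0.80), Scel (-3.44, SE 0.50), Kcnip2 (-3.32), Aff3 (-2.92, SE 0.30) and Eef2k (-2.90). Of 15 T cell identity genes 1 rose and 1 fell (1 and 0 adjusted over the list alone and with the set block; median -0.12, camera adjusted p = 0.781).

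**Figure D3:**
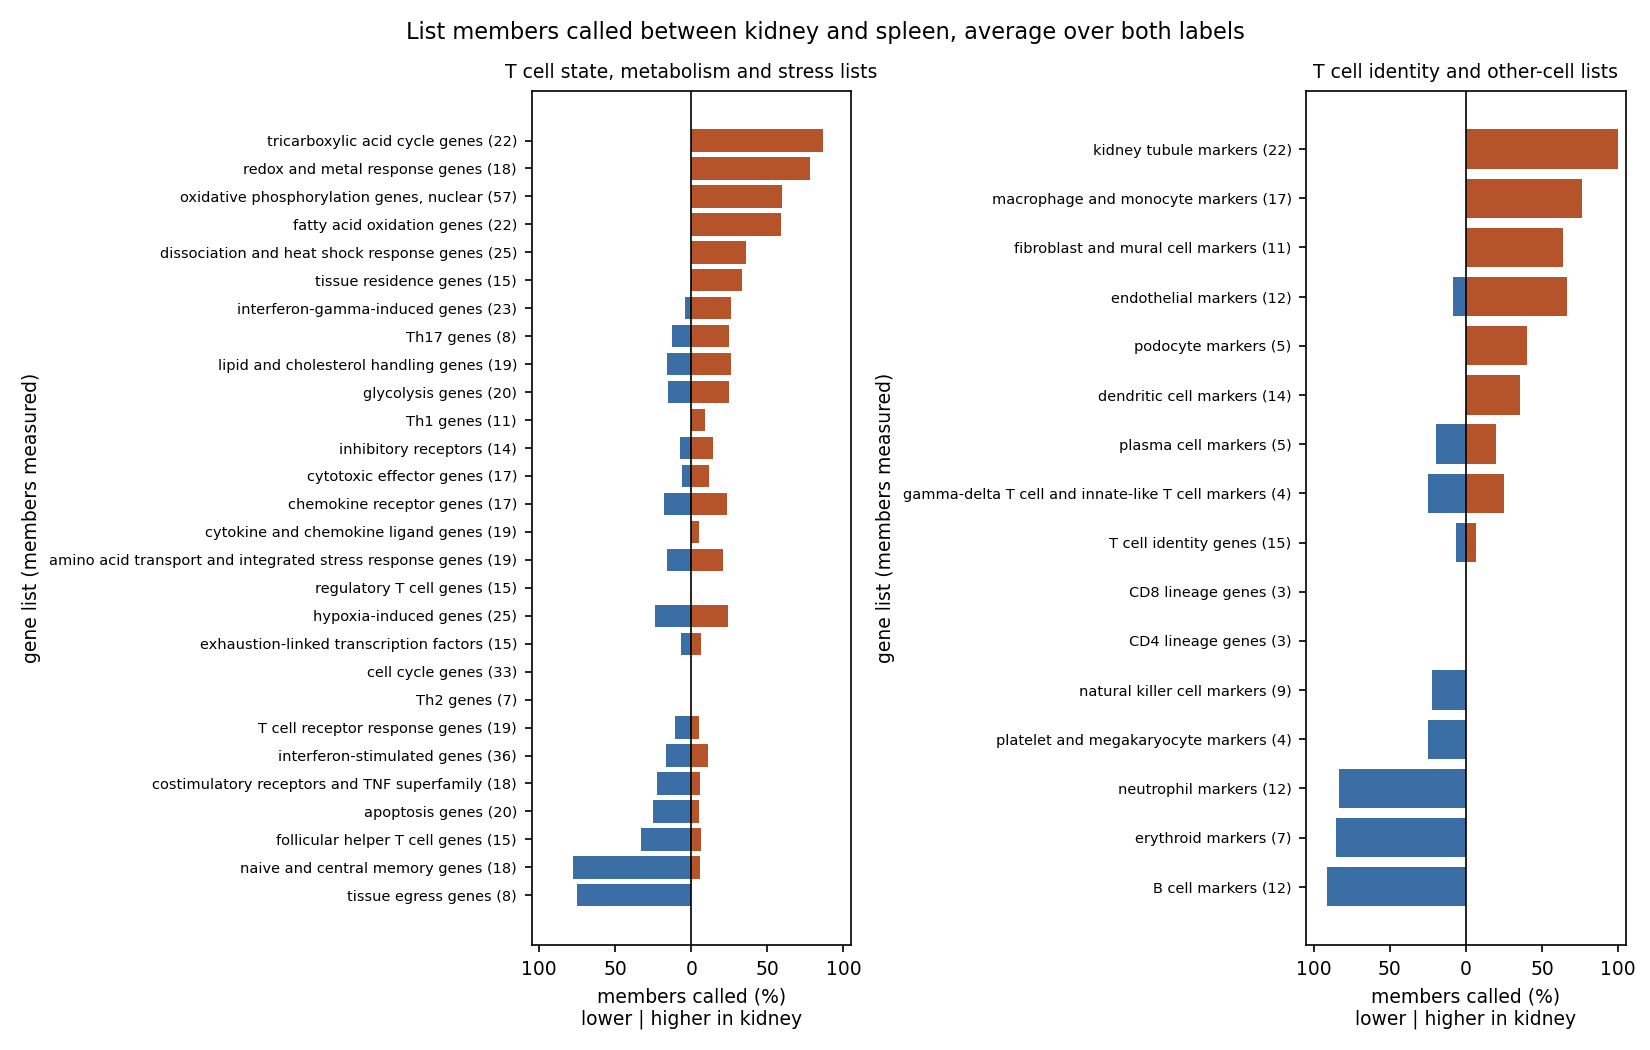
Share of the measured members of each gene list (percent) called lower or higher in kidney than in spleen, averaged over both labels (limma, adjusted p below 0.05, 6 against 6 libraries). All 22 tubule markers were higher and 14 of 18 naive and central memory genes were lower.

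In all, 6993 of 15814 genes differed in the average, 2459 higher and 4534 lower in kidney (limma, Benjamini-Hochberg), and 5693 with the set block, 2180 higher and 3513 lower, of which 5683 were in both. The median of all genes was -0.20 (-0.18 after centring each library on its median), so a list median near -0.20 lies with the bulk. Without the 4 libraries numbered 2, 7601 genes differed, 6202 of them shared with the 12 libraries.

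Within the libraries labelled CD4 (3 against 3), 4 of 15 residence genes rose and 10 of 18 naive and central memory genes fell. Cxcr6 rose by 2.88 (SE 0.42, limma adjusted p = 6.2e-04), Itga1 by 4.46 (SE 0.59, limma adjusted p = 3.31e-04) and Cdh1 by 4.81. Foxp1 fell by 1.26 (SE 0.13, limma adjusted p = 5.19e-05) and Bach2 by 2.34 (SE 0.31, limma adjusted p = 3.3e-04). Pdcd1 was at 9.67 ± 0.41 in kidney and 8.11 ± 1.45 in spleen (SD, n = 3 each), a log2 difference of 1.56 that did not pass (SE 0.67, limma adjusted p = 0.108). It fell to 0.73 without CD4 spleen 2 (limma adjusted p = 0.331) and to 0.57 without the 4 libraries numbered 2 (0.241; range over its alternatives 0.0769 to 0.396). Not called either were Ctla4 (2.05, limma adjusted p = 0.221), Tox (0.66, limma adjusted p = 0.43) and Cd69 (0.42, limma adjusted p = 0.459).

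Of 18 naive and central memory genes 10 fell and 1 rose in the libraries labelled CD4 (11 and 1 adjusted over the list alone, 5 and 1 with the set block; median -1.25, camera adjusted p = 0.0026; adjusted p = 0.581 with an estimated correlation). Of 15 residence genes 4 rose and 0 fell (5 and 0 adjusted over the list alone; median 1.21, camera adjusted p = 1.8e-04; adjusted p = 0.372 with an estimated correlation). Of 57 oxidative phosphorylation genes 19 rose and 0 fell (33 and 0 adjusted over the list alone, 10 and 0 with the set block; median 0.37, camera adjusted p = 8.36e-12; adjusted p = 0.511 with an estimated correlation), beside 22 of 22 tubule markers (median 9.92, camera adjusted p = 1.29e-35; adjusted p = 0.0881 with an estimated correlation). Of 22 tricarboxylic acid cycle genes 16 rose, 19 adjusted over the list alone and 9 with the set block (median 0.52, camera adjusted p = 7.58e-10; adjusted p = 0.372 with an estimated correlation). Of 12 B cell markers 9 fell, 10 adjusted over the list alone (median -3.13, camera adjusted p = 1.1e-04; adjusted p = 0.372 with an estimated correlation). The inhibitory receptors held 0 called genes of 14 (0 adjusted over the list alone; median 0.65, camera adjusted p = 0.152), and the list passed without CD4 kidney 3 (0.0329) or CD4 spleen 3 (0.0162; range over its alternatives 0.0162 to 0.866). Without the 4 libraries numbered 2 its median was -0.06 (camera adjusted p = 0.777). In the same 8 libraries that of the exhaustion-linked list turned from 0.66 to -0.13 (camera adjusted p = 0.852) and Tox was at -0.13 (limma adjusted p = 0.826). The positive medians in the libraries labelled CD4 thus rest on the libraries with the marker of the other cell type.

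Among the highest called genes in the libraries labelled CD4 were Slc27a2 (11.33), Fbp1 (10.62), Timp3 (10.57) and Tmem27 (10.57). Within the same limits on level, overlap and lists of other cells, the lowest were Wnt10a (-3.94, SE 1.18, limma adjusted p = 0.033; 0.0528 with the set block), Scel (-3.82, SE 0.70), Kcnip2 (-2.98), Kcnip3 (-2.98) and Pde2a (-2.70, SE 0.53), a cyclic nucleotide phosphodiesterase that fell from 9.44 ± 0.10 to 6.74 ± 0.77 (SD, n = 3 each). Wnt10a was not called without CD4 kidney 2, CD4 kidney 3, CD4 spleen 1 or CD4 spleen 3 (highest limma adjusted p = 0.112). Kcnip2 was not called without CD4 kidney 2, CD4 kidney 3 or CD4 spleen 3 (highest 0.0674), nor Kcnip3 without CD4 kidney 3, CD4 spleen 1 or CD4 spleen 3 (highest 0.0943). In all 3908 genes differed (limma), 1741 higher and 2167 lower, against 2420 with the set block, 1324 higher (54.7%) and 1096 lower, 2418 of them shared. The count was 2217 without CD4 kidney 3 and 2500 without CD4 spleen 3.

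Within the libraries labelled CD8 (3 against 3), Cxcr6 rose by 3.01 (SE 0.42, limma adjusted p = 4.82e-04), Itga1 by 4.56 and Cdh1 by 4.48, while Bach2 fell by 2.58 (SE 0.31, limma adjusted p = 1.7e-04) and Foxp1 by 1.35. S1pr1 fell by 2.22 (SE 0.41, limma adjusted p = 0.00337). Irgm1, an interferon-gamma-induced GTPase, rose by 1.27 (SE 0.24, limma adjusted p = 0.00406). Cd69 fell by 1.51 (SE 0.40, limma adjusted p = 0.0224; 0.0518 with the set block), and was not called without CD8 kidney 1, CD8 spleen 1 or CD8 spleen 3 (highest adjusted p = 0.0898).

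Of 18 naive and central memory genes 13 fell and 1 rose in the libraries labelled CD8 (15 and 1 adjusted over the list alone, 10 and 1 with the set block; median -1.94, camera adjusted p = 5.12e-05; adjusted p = 0.488 with an estimated correlation). Of 15 residence genes 3 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.52, camera adjusted p = 0.0101; adjusted p = 0.546 with an estimated correlation). This list was not called by fry (0.104) or without CD8 spleen 3 (0.053; range over its alternatives 2.13e-04 to 0.546). Of 8 egress genes 5 fell, 6 adjusted over the list alone (median -2.01, camera adjusted p = 0.00372; adjusted p = 0.505 with an estimated correlation). The egress list was not called without the members it shares with other lists (0.0927; range over its alternatives 5.23e-05 to 0.505). Of 23 interferon-gamma-induced genes 5 rose and 0 fell, the same adjusted over the list alone and 2 and 0 with the set block (median 0.50, camera adjusted p = 0.00146; adjusted p = 0.673 with an estimated correlation), and this list was not called by fry (0.257) or without CD8 spleen 3 (camera adjusted p = 0.0628; range over its alternatives 2.83e-05 to 0.673). Of 57 oxidative phosphorylation genes 5 rose, with 0 adjusted over the list alone and 0 with the set block (median 0.24, camera adjusted p = 1.15e-06; adjusted p = 0.673 with an estimated correlation and 0.185 by fry; range over its alternatives 1.83e-12 to 0.673). All 22 tubule markers rose (median 9.27; adjusted p = 0.14 with an estimated correlation) and 7 of 12 B cell markers fell, 10 adjusted over the list alone (median -2.95; adjusted p = 0.488 with an estimated correlation).

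Pdcd1 was at 9.48 ± 0.61 in kidney and 7.82 ± 1.03 in spleen in the libraries labelled CD8 (SD, n = 3 each), a log2 difference of 1.66 that did not pass (SE 0.67, limma adjusted p = 0.0981; range over its alternatives 0.00234 to 0.35). It passed without CD4 spleen 2 (limma adjusted p = 0.0278) and without CD8 spleen 2 (0.0337). Without the 4 libraries numbered 2, Pdcd1 was higher by 2.46 (SE 0.35, limma adjusted p = 0.00234) and Tox by 1.67 (SE 0.40, limma adjusted p = 0.0183; range over its alternatives 0.0183 to 0.685). In the same 8 libraries, 4 of 14 inhibitory receptors were higher and 1 lower (median 1.24, camera adjusted p = 0.0047), 3 of 15 exhaustion-linked transcription factors were higher (median 0.95, camera adjusted p = 0.0053) and 6 of 17 cytotoxic genes were higher (median 0.87, camera adjusted p = 2.96e-04). In all 12 libraries the inhibitory receptors gave 0 higher and 1 lower (0 and 1 adjusted over the list alone; median 0.90, camera adjusted p = 0.142), the exhaustion-linked list 0 called (median 0.63, camera adjusted p = 0.158) and the cytotoxic list 1 higher (median 0.77, camera adjusted p = 0.0594). The inhibitory and exhaustion-linked lists passed without CD8 spleen 2 (camera adjusted p = 0.0358 and 0.0115), and the cytotoxic list without CD4 kidney 2, CD8 kidney 2 or CD8 spleen 1 (0.0236, 0.0168 and 0.012). The cytotoxic list also passed with the set block (0.0403), the replicate block (0.049) and kidney-spleen pairs by label and number (0.00144), and over genes above the median level (0.0106). Over all alternatives the adjusted p ran from 0.00206 to 0.873, 0.00206 to 0.962 and 1.35e-05 to 0.817 for these lists.

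Among the highest called genes in the libraries labelled CD8 were Slc27a2 (11.17), Keg1 (10.67), Fbp1 (10.52) and Tmem27 (10.50). Within the same limits on level, overlap and lists of other cells, the lowest were Pou2af1, a B cell and follicular helper cofactor, at -5.42 (SE 0.89, limma adjusted p = 0.00164; 1.67 ± 0.19 in kidney and 7.09 ± 1.24 in spleen, SD, n = 3 each), Rgs9 (-4.79, limma adjusted p = 0.0422; 0.0785 with the set block), Gucy1a3 (-4.58), Ankrd13b (-4.52, SE 0.81) and Treml2 (-4.42). Rgs9 was not called without CD4 kidney 3, CD8 kidney 1, CD8 kidney 3, CD4 spleen 1, CD8 spleen 2 or CD8 spleen 3 (highest limma adjusted p = 0.14). Gucy1a3 was not called without CD8 kidney 1, CD8 kidney 2 or CD8 spleen 3 (highest 0.066), nor Treml2 without any of those or CD8 spleen 1 (highest 0.0822). In all 3293 genes differed (limma), 1541 higher and 1752 lower, against 1963 with the set block, 1143 higher (58.2%) and 820 lower, 1962 of them shared. The count was 1703 without CD8 kidney 1, 2195 without CD8 kidney 3, 1725 without CD8 spleen 1 and 2075 without CD8 spleen 3, and 4862 without the 4 libraries numbered 2.

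The tissue difference was tested for dependence on the cell type label by an interaction. For Pdcd1 it was 0.10 (SE 0.95, limma adjusted p = 1). Each label held libraries of both markers, so an interaction by label cannot show whether the difference depends on the cell type by marker. No list had a called member, since 0 genes passed in limma, with 549 at an unadjusted p below 0.05 and 336 with the set block. Of the lists, 15 passed camera and 0 passed with an estimated correlation. The interferon-gamma-induced genes had a median of 0.44 towards CD8 (camera adjusted p = 3.91e-04; adjusted p = 0.734 with an estimated correlation) and the macrophage markers -1.01 (camera adjusted p = 8.85e-06; adjusted p = 0.734 with an estimated correlation). Without the libraries numbered 2 the interaction for Pdcd1 was 1.89 (SE 0.49, limma adjusted p = 0.2), with 0 genes called in limma and 2177 at an unadjusted p below 0.05. By marker, the libraries with Cd8a above Cd4 had Pdcd1 at 9.24 to 10.18 in kidney and 6.44 to 7.59 in spleen. Those with Cd4 above Cd8a had it at 9.03 to 9.82 in kidney and 8.83 to 9.05 in spleen. An interaction by marker was not tested.

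The calls in both labels overlapped. Of the genes called, 1297 were higher in kidney in both labels, where independent lists give 169.7 (Fisher's exact test, odds ratio 165, log10 p = -1231.1), 957 were lower in both, where independent lists give 240.1 (odds ratio 12.8, log10 p = -430.2), and 1 was called in opposite directions. Across genes, which are not independent replicates, the log2 differences had a Pearson correlation of 0.92 and a Spearman correlation of 0.817. These comparisons share no library, but each label holds both cell types by marker and both share the second centred set. Without the 4 libraries numbered 2 the odds ratios were 49.6 and 5.73, 19 genes were called in opposite directions, and the correlations were 0.855 (Pearson) and 0.698 (Spearman). With the set block 1014 genes were higher and 383 lower in both, and the sum of 2254 fell to 1392 without CD8 kidney 1 and to 1434 without CD8 spleen 1.

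**Figure D4:**
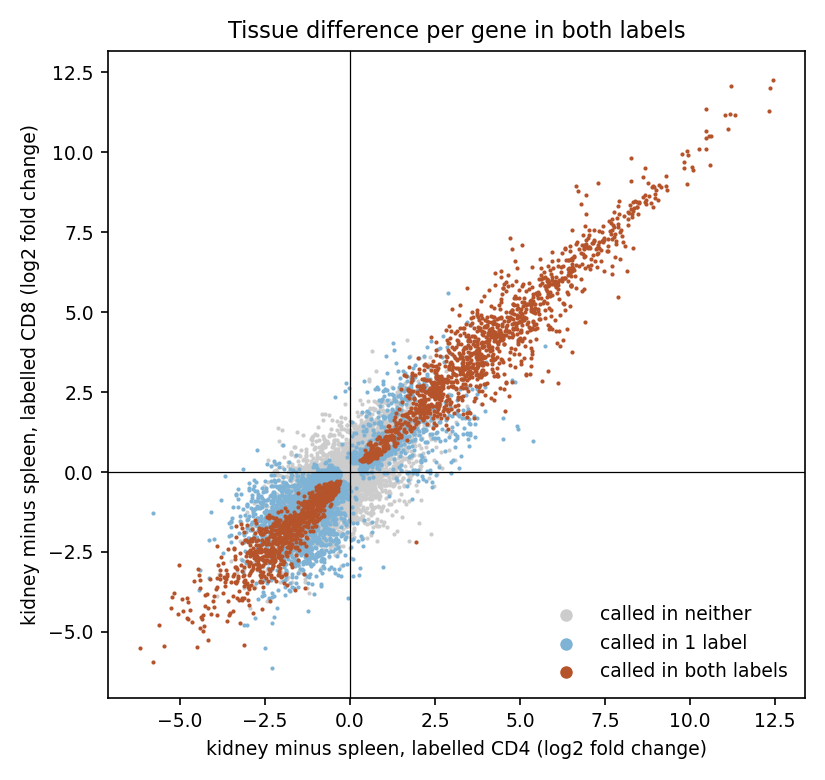
Log2 difference of kidney minus spleen for each of 15814 genes, in the libraries labelled CD4 (horizontal) and labelled CD8 (vertical), coloured by calls in neither, 1 or both labels. The 1297 genes higher in both and the 957 lower in both lie along the diagonal (Pearson correlation 0.92 across genes).

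CD8 against CD4 within a tissue gave 0 genes by label in limma, in the kidney with 208 and in the spleen with 200 genes at an unadjusted p below 0.05 (634 and 533 with the set block, 0 called). Cd4, Cd8a and Cd8b1 were not called, since 1 library of each label carried the other marker. Without the 4 libraries numbered 2, left out because of Cd4 and Cd8a, 196 genes differed in the kidney, 104 higher in CD8 and 92 lower, and 1691 in the spleen, 824 higher and 867 lower. With the set block added these were 18 and 28, in a fit where only the second set held both labels. The differences in Cd4 and Cd8a follow from the choice of libraries.

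In these 8 libraries Gzmm, encoding granzyme M, was higher in kidney CD8 by 5.83 (SE 0.42, limma adjusted p = 0.00152; 0.00967 with the set block and 1 in all 12 libraries), and Cd40lg, the ligand by which helper cells stimulate B cells, was lower, at -8.41 (SE 0.39, limma adjusted p = 3.74e-04; 0.0128 with the set block and 1 in all 12 libraries). In the kidney 8 of 17 cytotoxic genes were higher in CD8 (median 1.61, camera adjusted p = 8.58e-15) and 6 of 15 regulatory T cell genes were lower (median -4.07, camera adjusted p = 1.27e-18). In the spleen 13 of 15 regulatory T cell genes (median -3.84, camera adjusted p = 2.39e-12), 8 of 15 follicular helper genes (median -1.69) and 6 of 15 exhaustion-linked transcription factors (median -1.63, camera adjusted p = 2.28e-06) were lower in CD8, and 6 of 18 naive and central memory genes were higher (median 1.09, camera adjusted p = 2.32e-05). In all 12 libraries 19 lists passed camera in the kidney and 11 in the spleen, and 0 passed with an estimated correlation. With the set block in the 8 libraries most member calls ended. In the kidney 3 cytotoxic and 0 regulatory T cell genes were called. In the spleen these were 1 regulatory T cell, 2 follicular helper, 0 exhaustion-linked and 0 naive and central memory genes. Lists in the 8 libraries were tested with the preset correlation alone.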

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

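The set block, the fits without the libraries numbered 2, the covariate, the paired differences per set and the kidney-spleen pairs were chosen after the result was seen. Over 31 alternatives, 7305 values of named genes gave 6667 with the same call, 621 no longer past the threshold and 17 newly past it, and the cause of these moves was not tested. The sign changed in 45, past the threshold in neither fit, 37 of them on leaving out 1 library. The other 8 came without the libraries numbered 2, with or without the set block: Lag3 in the average (-0.31) and Havcr2 (-0.88), Tigit (-0.43) and Tox (-0.13) in CD4. Depth is unknown and sets no limit that could be computed here. Alternatives on counts, pseudocounts and depth were not run, and no filter was the choice already in use. Removing genes of other cells left 15682 genes and changed no call of a named gene. The values of the remaining genes stay the same in that fit, so it does not test for RNA of other cells.

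Kidney-spleen counts for the labels CD4 and CD8 and the average were, for a fold change above 1.5, 1433, 1392 and 2350, at an adjusted p below 0.01, 1705, 1426 and 4018, and over the 7907 genes above the median level, where fewer genes were tested, 1031, 528 and 2475. Fitting only the 2 groups gave 2412 for CD4. The set block gave 2420 for CD4 and 1963 for CD8, and an overlap of 1397 against 2254. The tissue difference averaged within each set gave 4496 against 6993, from 3 differences. Without the libraries numbered 2, CD8 against CD4 gave 196 genes in the kidney and 1691 in the spleen. Together with the set block these were 18 and 28, with 1089 for CD4, 1675 for CD8, 4036 for the average and an overlap of 745. In that last fit the cell cycle list was lower in CD4, with a median of -0.55 (camera adjusted p = 0.0143; range over its alternatives 9.55e-04 to 1). It was higher there without CD4 kidney 3 (median 0.47, camera adjusted p = 9.55e-04) or CD4 spleen 3 (0.30, 0.022).

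With an estimated correlation 0 lists were called in the average, CD4 and CD8, against 18, 16 and 17, while fry ended 4 and added 8 list calls. The tubule markers, all called higher, also failed with an estimated correlation (adjusted p = 0.144, 0.0881 and 0.14). The loss of these calls thus cannot tell lists that moved from lists that did not. Leaving out 1 library gave 2217 to 4212 genes for CD4, 1703 to 4267 for CD8, 5596 to 7399 for the average, 1392 to 2556 for the overlap, 0 to 0 for the interaction and for CD8 against CD4 in either tissue, and 15 to 21, 14 to 23 and 15 to 21 lists in the average, CD4 and CD8. Lowest counts came without CD4 kidney 3 (CD4), CD8 kidney 1 (CD8, overlap) and CD8 spleen 1 (average), and the highest for these came without CD8 spleen 2.

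Whether same-numbered libraries deviate together could not be decided, since centring pulls correlations within a set below 0. Of 18 same-number pairs 4 had a correlation above 0.1 (range -0.674 to 0.299). Kidney-spleen pairs of 1 label and number had 0.05 to 0.299 outside the second set, where other kidney-spleen pairs had -0.521 to -0.32, but such pairs there also share the marker. In the second set they had -0.508 and -0.356, and the others -0.492 and -0.485. These 6 pairs as a block gave 2568 genes for CD4, 2277 for CD8, 6175 for the average and an overlap of 1482. The interaction gave 0 in limma, with 370 at an unadjusted p below 0.05. A replicate block gave 2101 genes for CD8, 2648 for CD4 and 5805 for the average, and 0 for the other comparisons. As a random effect it gave 2334, 2837 and 5910.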

Other observations

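Of the tests below, those of exchanged labels, mixed libraries, column order, diluted T cell transcripts, B cell RNA and the splits inside the centred sets were chosen after the result was seen, as were the set block, the kidney-spleen pairs and the fits without the libraries numbered 2. The tubule correlation and the other splits were written before.

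Other immune programmes were compared between kidney and spleen in the average over both labels. Of 15 follicular helper genes 5 fell and 1 rose (5 and 1 adjusted over the list alone; median -0.31, camera adjusted p = 0.781), among them Cxcr5, which draws cells to B cell follicles, at -2.59 (SE 0.40) and Pou2af1 at -4.28 (SE 0.63). B cells express both genes, and 11 of 12 B cell markers fell in the same comparison (median -2.82), so the fall is not assigned to T cells here. In spleen, however, all B cell markers together took 0.00536% to 0.0118% of the summed antilogs. Their mean log2 value was 1.20 to 2.79 per spleen library, while Cxcr5 alone had log2 values of 7.27 to 9.03. These values argue against B cell RNA as the main source of Cxcr5 in the spleen libraries. Pou2af1 had values of 4.55 to 8.53 there, and for it the source stays open. What part of the fall B cell RNA could carry was not tested. Of 8 Th17 genes 2 rose and 1 fell (5 and 1 adjusted over the list alone; median 1.11, camera adjusted p = 0.0291; adjusted p = 0.516 with an estimated correlation), with Tmem176b at 5.27 (SE 0.38) and Tmem176a at 5.23, both also expressed by myeloid cells. That list was not called without CD8 kidney 2 (adjusted p = 0.05) or CD4 spleen 2 (0.0592; range over its alternatives 2.79e-04 to 0.516). Of 23 interferon-gamma-induced genes 6 rose and 1 fell (3 and 0 adjusted over the list alone, 4 and 0 with the set block; median 0.32, camera adjusted p = 0.0198; adjusted p = 0.867 with an estimated correlation), and the list was not called without CD8 kidney 2, CD4 spleen 2 or CD8 spleen 3 (0.0645, 0.0892 and 0.119) or by fry (0.362; range over its alternatives 0.00323 to 0.867). Of 36 interferon-stimulated genes 4 rose and 6 fell (4 and 6 adjusted over the list alone; median -0.15, camera adjusted p = 0.89), with Oasl2 at 3.58 and Trim30d at -2.31. Of 17 cytotoxic genes 2 rose and 1 fell (1 and 1 adjusted over the list alone; median 0.50, camera adjusted p = 0.159; 0.0255 with kidney-spleen pairs by label and number and 0.0493 over genes above the median level; range over its alternatives 0.0255 to 0.925), with the death ligand gene Tnfsf10 at 1.27 (SE 0.12) and Crtam at -1.34 (SE 0.28).

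Of 19 cytokine and chemokine ligand genes 1 rose, Spp1 or osteopontin, at 3.47 (SE 0.87; camera adjusted p = 0.213). Its values were highest in CD4 kidney 3 and CD8 kidney 1 (11.1 and 10.3), the libraries with the highest tubule marker means, so its rise cannot be assigned to T cells. Of 17 chemokine receptors 4 rose and 3 fell (adjusted p = 0.658), of 15 regulatory T cell genes 0 and 0 (0.355), of 11 Th1 genes 1 and 0 (0.551), of 7 Th2 genes 0 and 0 (0.781) and of 19 T cell receptor response genes 1 and 2 (0.781), with Egr3 at -2.89. Of 18 costimulatory genes 1 rose and 4 fell (0.89), and of 33 cell cycle genes 0 and 0 (0.408). Glycolysis gave 5 higher and 3 lower of 20 (0.33; 0.0316 over genes above the median level; range over its alternatives 0.0316 to 0.952), hypoxia 6 and 6 of 25 (0.144; 0.0372 by fry; range over its alternatives 0.0372 to 0.634), lipid and cholesterol handling 5 and 3 of 19 (0.0777; called without CD8 kidney 1, CD4 spleen 3 or CD8 spleen 2 at 0.0478, 0.0239 and 0.037, with kidney-spleen pairs at 0.0423 and by fry at 0.0188; range over its alternatives 0.0188 to 0.445), amino acid transport and stress 4 and 3 of 19 (0.599) and apoptosis 1 and 5 of 20 (0.989). The cell cycle list was called without CD4 kidney 3 (0.0143; range over its alternatives 0.0143 to 0.977). Among other cells, dendritic markers gave 5 higher and 0 lower of 14 (camera adjusted p = 0.0386; adjusted p = 0.445 with an estimated correlation), not called without CD4 kidney 2, CD8 kidney 2 or CD4 spleen 2 (0.0574, 0.05 and 0.0708), nor without the 4 libraries numbered 2 (0.0862, and 0.0701 with the set block; range over its alternatives 1.52e-04 to 0.445). Podocyte markers gave 2 and 0 of 5 (0.153; 2.48e-05 by fry; range over its alternatives 2.48e-05 to 0.445), plasma cell 1 and 1 of 5 (0.769), platelet 0 and 1 of 4 (0.551; 0.0234 by fry; range over its alternatives 0.0234 to 0.916), natural killer 0 and 2 of 9 (0.712) and gamma-delta T cell 1 and 1 of 4 (0.999). The CD4 lineage list gave 0 and 0 of 3 (0.781), as did the CD8 lineage list. Adjusted over the list alone, chemokine receptors gave 2 and 3, costimulatory genes 1 and 3, and apoptosis 0 and 1 (0 and 2 with the set block), and the others in this paragraph kept their counts.

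Because camera sets a list against the other genes, whose median was -0.20, its direction was up for lists with medians below 0, namely chemokine receptors (-0.19), interferon-stimulated genes (-0.15), apoptosis (-0.17), T cell identity (-0.12), amino acid transport (-0.04), CD8 lineage (-0.06) and dendritic markers (-0.03). The last 3 of these, like the Th1 list, had means above 0. The gamma-delta T cell list had a median of -1.0 and a mean of -0.719, both below that of all genes, while camera gave up at a p of 0.999. Glycolysis, Th2, T cell receptor response, costimulatory and plasma cell lists had medians above 0 and means below 0.

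A first pattern was the set of lineage markers against the label in the 4 libraries numbered 2. A mixture of both cell types is argued against, since the labelled marker lay at least 7.89 log2 units below the other (up to 12.37). Outside the lineage lists, 4 of 4 of these libraries correlated better with the other label, consistent with exchanged labels as a candidate explanation. In the 3 centred sets, 6 of 6 same-tissue pairs held 1 library with each marker. In 1 tissue, 6 of 15 pairings give this. Pairings drawn independently in both tissues give it in 16%, but here both tissues were paired alike, so 16% is too low. A column order other than the one the labels follow may also account for the markers. Under both explanations cell type follows Cd4 and Cd8a and not the label, so these values cannot tell them apart. The split of a tissue by these markers gave 426 genes in the kidney and 3617 in the spleen, against 0 by label. Both explanations stay open, and no biological one was tested.

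A second pattern was the rise of mitochondrial and fatty acid oxidation genes in kidney. RNA of tubule cells could account for it: over 6 kidney libraries the called members rose with the tubule markers (Pearson r = 0.958, exact permutation p = 0.0111, Benjamini-Hochberg 0.0222 over 4 relations; Spearman 0.886, exact permutation p = 0.0333). Without the 2 farthest libraries, CD4 kidney 3 and CD8 kidney 1, which share a centred set, r was 0.092, so the relation rests on them and tubule RNA cannot be told apart from a change in the T cells. The identity genes averaged -0.03 with bounds of -0.165 and 0.105, which leaves a small dilution of T cell transcripts open. Sorting on surface markers should remove tubule cells but not free RNA, and a metabolic difference of kidney T cells stays open.

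The last pattern weighed was the fall of naive and central memory genes in kidney. RNA of B cells in the spleen libraries is argued against as the whole source, since 5 of 7 members that B cells hardly express fell too. Dilution in kidney is argued against, since the list's median lay -1.68 from that of the identity genes. Fewer naive cells among kidney T cells is then a hypothesis, not tested on other data.

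Other splits of the libraries were counted. For the average, 1 of 100 drawn splits, the real one, gave as many as 6993 genes and the highest other gave 2, but these splits did not keep the centred sets. Of the 72 splits inside the sets, fitted with the set block, 1, the real one, gave as many as 5693 genes and the highest other gave 1, so a chance split can be excluded. For CD4 and CD8, fitted on 6 libraries, the real splits gave 2412 and 2631 genes and the highest other 0, but 10 splits are too few for a share under 0.05. For the interaction 100 of 100 splits gave as many as the real 0, which any split reaches, so this count decides nothing. The highest other gave 2227, in a split that does not part the libraries by Cd8a and Cd4 in both tissues. Whether it parts them by these markers in 1 tissue alone was not looked at, so the source of this count stays open. For CD8 against CD4 10 of 10 splits in each tissue gave at least the real 0 of limma, where a share under 0.05 is out of reach, and the highest others gave 426 in the kidney and 3617 in the spleen, both in the split that parts libraries by Cd8a and Cd4.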
